A study of Mus musculus with 2 samples.

How the data were processed

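The data are RNA-seq measurements from 2 libraries of mouse lung epithelial cells, 1 library per genotype. Per the labels, adult mice received doxycycline food at 625 mg/kg for 16 days, cells negative for lineage markers, positive for CD326 (Epcam) and intermediate for CD24 were sorted from lung, and RNA was extracted with the RNeasy Micro kit. Each library was made with the Nextera XT kit from RNA pooled from 4 mice of 1 genotype. The control mice carried the Cre transgene under the tetracycline operator and floxed Mst1 and Mst2 alleles. The other mice also carried the reverse tetracycline transactivator under the Scgb1a1 promoter, which is needed for doxycycline to switch on Cre. The genotypes therefore differ in the transactivator and in active Cre as well as in the intended deletion. Effects of these cannot be told apart here. The mice of a pool cannot be told apart, so there is no replicate error for any value, and no difference between these libraries has a replicate check.

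Each library has 1 table with 28107 rows, 1 per RefSeq transcript entry, for 22072 gene symbols. The same 28107 entries are in both tables. Per the submitters' processing notes, TopHat and Cufflinks were used with the mm9 genome build; their versions, the read length, the strandedness and the other settings are not given in the sources used here. Per the file headers, each row holds an FPKM value that the authors deposited (fragments scaled by transcript length and by the mapped fragments of the library), a transcript length and an estimation status. Per the file headers, each row also holds the authors' coverage, a signal that gives the mean depth of reads over the transcript. The tables used here give no confidence interval for FPKM. The start positions count from 0, since 99.5% of 655 microRNA rows then span exactly their stated length; the starts printed are raised by 1 so that they count from 1.

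Library depth was inferred from the coverage column, because read counts are not given in the tables used. Coverage times transcript length sums to 413 Mb in the control library and 393 Mb in the library labelled Mst1/2-deleted. The ratio of coverage to FPKM is constant within a library and implies 1275 and 1141 Mb behind the FPKM denominators, a depth ratio of 0.895. For low rows of genes with a single transcript, the median of values between 25 and 75 bases, 47.1 bases, was taken as 1 read. The window was a choice, so this size is an assumption. It puts about 8780000 and 8340000 reads on the listed transcripts. Whole reads could not be recovered: of single-transcript rows worth about 1 to 10 reads, 25.9% in the control library and 25.6% in the other lay within 0.1 of a whole read. No count test was therefore run. The approximate reads were used for the simulations described below and for a floor of 3 reads for list members listed at 0. Rounded, they also gave an exact (Clopper-Pearson) 95% interval of each FPKM ratio, scaled by the depth ratio. These intervals cover counting error only, not differences between mice, sorts or library preparations, and amplified reads are not independent molecules. The status was OK for 27791 control rows and 27760 rows of the other library, LOWDATA for 294 in each, FAIL for 21 and 52, and HIDATA for 1 in each. The HIDATA row is Scgb1a1, the gene of the most abundant club cell secretory protein, which is listed at 0 in both libraries. HIDATA marks a locus with too many reads for Cufflinks to estimate, so this 0 is a failed estimate, and Scgb1a1 could not be measured.

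FPKM was summed over rows that share a gene symbol. The difference of a gene is log2((FPKM + 1) in the library labelled Mst1/2-deleted over (FPKM + 1) in the control library). The pseudocount of 1 understates the differences of low genes, so ratios of FPKM without it are given for named genes. Genes entered with FPKM of at least 1 in at least 1 library, and genes at least 2-fold apart on the log2(FPKM + 1) scale were counted. For comparison, counting error alone was simulated 100 times by redistributing the approximate reads of each gene between the libraries. For a gene listed at 0 in 1 library no fold is given. FPKM is computed per transcript from reads that can fit several transcripts, so values of near-identical family members and of overlapping genes depend on how Cufflinks shared such reads, and the strand was not available to separate antisense neighbours.

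The gene lists, numbering 30, were fixed before the data were examined, as were the fold rule, the random-list comparison and the main alternative settings. For each list with at least 5 members at FPKM of at least 1, the median difference was compared with medians of 10000 random lists of the same size matched on mean expression in 20 bins. A list is said to stand apart when its percentile is under 2.5 or above 97.5. Members at least 1.5-fold higher or lower on the log2(FPKM + 1) scale were counted. The percentile describes these 2 libraries. Genes of a list tend to vary together between any 2 samples, which random lists do not, so the percentile is lenient: 19 of 26 lists stood apart, against 1.3 expected from unrelated genes.

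The genes named in the text were chosen by a rule fixed in advance. It took Stk3 and Stk4, the 12 genes most higher and the 12 most lower among genes with FPKM of at least 5 in at least 1 library and status OK in both, up to 4 members of each list with the largest difference (up to 8 for the Hippo component and Yap/Taz target lists), and a set of airway, alveolar, proliferation, leukocyte, endothelial, mesenchymal and sex-linked genes. The genes described in the closing observations, 3 lists used there (alveolar macrophage, proximal airway and secreted defence genes), and other genes named outside the rule were chosen after their values were seen. A few genes that the rule takes are not reported here.

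The alternatives set in advance were pseudocounts of 0.1 and 5, scaling to a median log2 ratio of 0, to the same upper quartile and to each library's FPKM sum (TPM), the highest row in place of the sum per symbol, no filter on low values, a filter at FPKM of 5, rows with status OK alone, folds of 1.5 and 4, and random lists without matching. Restricting the count to transcripts of at least 300 bases, with and without status OK, matching random lists on expression (10 bins) and transcript length (5 bins), and removing a cubic trend in transcript length and GC content were added after seeing the data. GC content came from GENCODE vM21 transcripts matched by RefSeq identifier or symbol, for 99.6% of genes and all measured list members; no coordinates were taken from it, because its build differs from mm9.

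The steps were tested on simulated data, drawn as Poisson counts from the mean approximate reads of both libraries. In a simulation of 9945 genes, of which those with transcripts of at least 300 bases were scored, the 2-fold rule found 88% of 100 genes changed 4-fold and 74% of 100 genes changed 3-fold, or 100% of 42 and 97.1% of 35 with FPKM of at least 5, and called 0% of 9621 unchanged genes. Of 200 simulated unchanged lists of 15 unrelated genes, 4.5% stood apart, and 100% of 50 lists of such size, drawn from genes with FPKM of at least 5 and shifted by 0.5 on the log2 scale, were found. The simulated data held counting error only, without differences between mice, sorts or library preparations. These rates therefore do not give the share of false calls between the 2 real libraries. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1 were used.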

Results

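RNA-seq was performed on sorted lung cells of adult mice after 16 days of doxycycline food. The sort (lineage-negative, CD326-positive, CD24-intermediate) was used to enrich secretory cells of the airway epithelium that carry no motile cilia. There were 2 libraries, each from the pooled RNA of 4 mice. In the control library, floxed Mst1 and Mst2 remained without a Cre activator. In the library labelled Mst1/2-deleted, doxycycline was meant to switch on Cre by way of the Scgb1a1 promoter of club cells. The genotypes thus also differed in the Cre activator and in active Cre. Mst1 and Mst2 (gene symbols Stk4 and Stk3) encode the upstream kinases of the Hippo pathway, which restrains the transcriptional coactivators Yap and Taz. About 8780000 reads lay on listed transcripts in the control library and 8340000 in the other. Genes with FPKM of at least 1 numbered 9537 and 9559. There was 1 library per genotype, so no difference could be set against a spread between replicates and no p-value is given. Intervals in the text are 95% intervals for counting error only. Members of gene lists were counted as 1.5-fold apart on the log2(FPKM + 1) scale, on which low genes differ less than in their FPKM ratios.

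The first comparison checked the deleted genes themselves. Neither was strongly reduced. Stk4 (chr2:163899914-163981257, mm9) had an FPKM of 5.38 in the control library and 4.71 in the library labelled Mst1/2-deleted, a ratio of 0.874 (interval 0.784 to 0.975). Stk3 (chr15:34805254-35085561) had FPKM of 7.28 and 7.09, a ratio of 0.975 (0.862 to 1.10). The exons removed by Cre are not stated in the labels, so a value over the whole transcript may include exons that remain. The share of sorted cells in which Cre acted is not known either. These values therefore neither check nor contradict the label, and the second library is called the library labelled Mst1/2-deleted throughout.

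The second comparison asked which transcripts differed between the libraries, in a design meant to delete Mst1 and Mst2 from mature airway epithelium. The profiles were close, with 94.4% of 9945 genes within 1.5-fold and a Pearson r of 0.969 across genes, which are not independent replicates. The median log2 difference of these 9945 genes was 0.07. The percentiles of lists allow for this shift, whereas list medians and counts of members above or below 0 do not. Most marker transcripts of alveolar type 1 cells were higher in the library labelled Mst1/2-deleted, with a median FPKM ratio of 1.86 and a range from 0.995 for Cav1 to 5.26 for Akap5. The Yap target Ctgf was 4.01-fold higher. The secretoglobins Scgb3a1 and Scgb3a2, mucous cell genes and the basal keratins Krt5 and Krt15 were lower. The abundant secretory cytochrome Cyp2f2 differed little, with FPKM of 4694 and 5305. At least 2-fold differences were counted for 75 genes in the higher and 97 in the lower direction. Of these, 24 and 33 had transcripts under 300 bases, small RNAs by their symbols. Without them and without genes lacking status OK, the counts were 48 and 60. Counting error alone gave medians of 8 and 9 genes over 100 simulated draws, and at most 1 in either direction among transcripts of at least 300 bases.

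**Figure D1:**
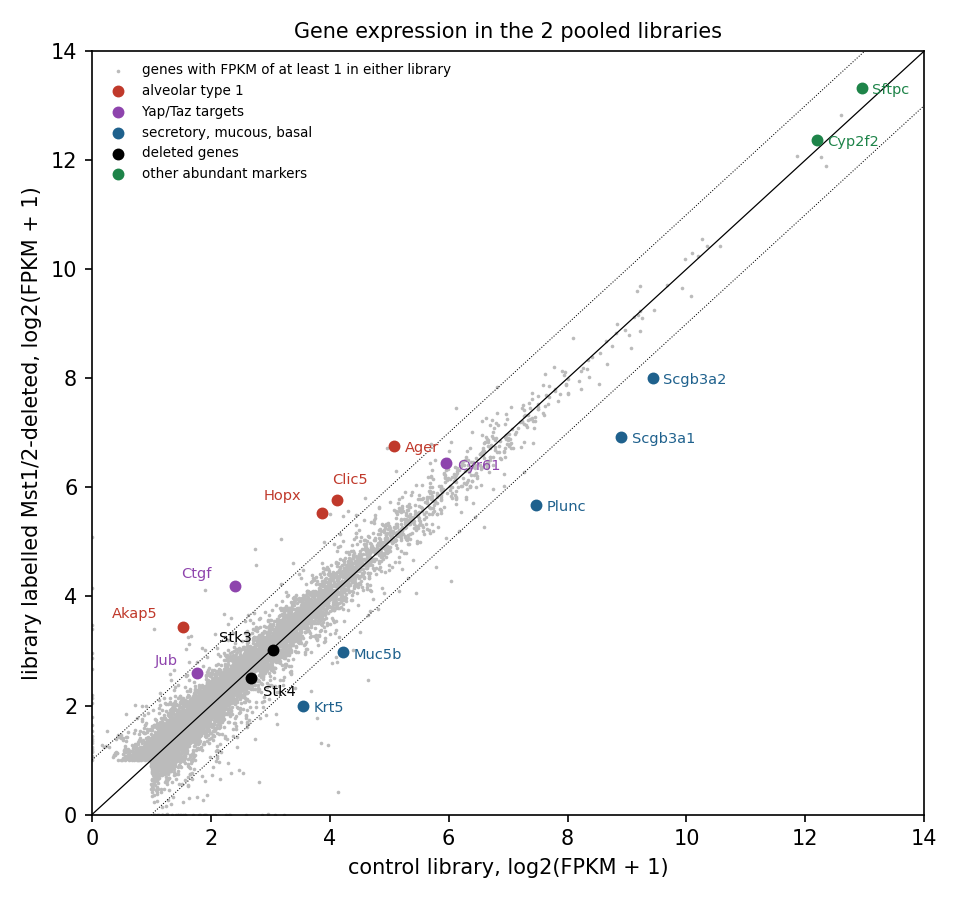
Expression of 9945 genes in the 2 libraries, as log2(FPKM + 1) in the control library (x axis) and in the library labelled Mst1/2-deleted (y axis), with named genes in colour. The solid line marks equal values and the dotted lines a 2-fold difference; Ager (FPKM 32.9 and 107) lies above the upper dotted line and Scgb3a2 (691 and 256) below the lower one.

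Among Yap/Taz target genes, Ctgf, a secreted matricellular protein gene, stood out. Its FPKM was 4.30 in the control library and 17.2 in the library labelled Mst1/2-deleted, 4.01-fold higher (3.52 to 4.61; chr10:24315248-24318488). Jub, which encodes the LIM protein Ajuba, was 2.10-fold higher (1.79 to 2.49; FPKM 2.39 and 5.02). Cyr61, the other classic secreted target, started from a higher level and differed less, 61.4 against 85.7, a ratio of 1.40 (1.33 to 1.46). Ptpn14 (ratio 1.67), Rbms3 (1.53), Tgfb2 (1.51) and Lats2 (1.47) were also higher, whereas Axl, a receptor tyrosine kinase gene, was 3.21-fold lower at low levels (FPKM 1.25 and 0.388). Amotl2 had FPKM of 4.17 and 5.12, and Areg 9.53 and 10.3. Of 21 measured targets, 16 lay above 0, with 2 at least 1.5-fold higher and 1 lower on the log2(FPKM + 1) scale. Their median log2 difference was 0.24, at the 99.88 percentile of random lists. This call ended when a transcript length and GC trend was removed (median 0.18, percentile 97.0, under the upper limit for standing apart), after conversion to TPM and without the filter on low values. Alveolar type 1 cell markers, described below, were higher in the same library.

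The Hippo pathway components as a list were slightly higher, with a median log2 difference of 0.19 at the 98.19 percentile. Only Wwc2, an upstream scaffold gene, passed 1.5-fold on the log2(FPKM + 1) scale among 22 members, at FPKM of 3.70 and 6.62. Wwc1 (16.2 and 23.7), Tead4 (1.63 and 2.78), Frmd6 (2.54 and 3.97), Tead1 (10.3 and 14.5), Vgll4 (4.64 and 6.46) and Amotl1 (3.07 and 4.28) were also higher, as was Lats2, given above. Yap1 had FPKM of 6.88 and 8.69, and Wwtr1, which encodes Taz, 5.68 and 6.39. The list no longer stood apart with the highest row per symbol (percentile 92.2), with the filter at FPKM of 5 (92.3) and with the length and GC trend removed (95.7).

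Most genes of the mitosis and DNA replication lists were under FPKM of 1 in both libraries. Among 25 mitosis genes, 5 reached FPKM of 1, and none of these differed by 1.5-fold on the log2(FPKM + 1) scale. Mki67, the Ki-67 gene, had FPKM of 1.05 and 1.35, Top2a 1.07 and 1.04, Ube2c 3.17 and 3.50, and Prc1 1.73 and 1.84. Ect2, at lower levels of 0.439 and 1.06, had an FPKM ratio of 2.42 (1.74 to 3.57). The mitosis median of 0.11 lay at the 68.95 percentile, and the list stood apart when all 25 genes were kept without a filter (percentile 98.4) or after conversion to TPM (98.5). Of 8 measured DNA replication genes, 0 differed by 1.5-fold, with a median of 0.15 at the 82.74 percentile. The largest difference among them was that of Mcm6, at 1.77 and 2.34. Pcna, the most abundant of them, had FPKM of 24.4 and 27.1. Ccnd1, the cyclin D1 gene, had FPKM of 48.9 and 54.3.

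Alveolar type 1 cell markers had the highest median of the 26 lists compared. Of 15 measured members, 12 were at least 1.5-fold higher and 0 lower in the library labelled Mst1/2-deleted, and the median log2 difference of 0.83 lay above all 10000 random lists. Ager, the receptor for advanced glycation end products and a membrane protein of type 1 cells, had FPKM of 32.9 and 107, 3.26-fold higher (3.05 to 3.48; chr17:34734807-34737877). Hopx, a homeodomain-only protein gene, was 3.34-fold higher (3.01 to 3.77; chr5:77516011-77544148). Clic5 was 3.27-fold higher (3.12 to 3.42) and the anchoring protein gene Akap5 5.26-fold higher (4.68 to 5.93). Aqp5 had FPKM of 20.3 and 32.3. Cav1, the caveolin gene, was an exception, at 6.32 and 6.29. The list of alveolar type 2 cell markers was also higher, with a median of 0.33 above all random lists, although only Lpcat1 passed 1.5-fold among 16 members (FPKM 93.7 and 149). Sftpc, the surfactant protein C gene, had FPKM of 7888 and 10270, Napsa 49.4 and 71.8, Etv5 45.9 and 65.2, and Slc34a2 573 and 780. Among genes whose estimate succeeded, Sftpc had the highest FPKM in both sorted pools.

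Secretory airway genes did not move as a block. The 19 measured club cell markers had a median of -0.16 at the 0.59 percentile, with 4 at least 1.5-fold lower and 1 higher. This median came within the random range once the length and GC trend was removed (-0.017, percentile 8.48). Scgb3a1 differed most, with FPKM of 477 in the control library and 121 in the other, 3.95-fold lower (3.72 to 4.17; chr11:49477112-49478620). Scgb3a2 was 2.70-fold lower (2.61 to 2.78), at 691 and 256 (chr18:43923981-43927053). Reg3g, a C-type lectin with antibacterial action, had FPKM of 39.0 and 19.1. In the other direction, the cytochrome gene Cyp2b10 was 2.46-fold higher (2.27 to 2.67). Cyp2f2, used as a club cell marker, had a ratio of 1.13 (1.12 to 1.14). Scgb1a1 could not be measured, since its estimate failed in both libraries.

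Mucous and basal cell genes were lower together. Of 7 measured mucous cell markers, 6 were at least 1.5-fold lower, with a median log2 difference of -1.25 below all random lists. The gel-forming mucin gene Muc5b had FPKM of 17.7 and 6.85, 2.58-fold lower (2.46 to 2.70). Clca3 was 3.52-fold lower (2.94 to 4.23) and the disulfide isomerase gene Agr2 5.10-fold lower (2.53 to 11.01). Tff2 had an FPKM of 1.80 in the control library and was listed at 0 in the other; placed at a floor of 3 reads, it left the list median at -1.20. Muc5ac was under FPKM of 1 in both, at 0.932 and 0.283. The basal and squamous list of 10 measured genes had a median of -0.50 at the 0.01 percentile, with 3 lower and 1 higher. Krt5 had FPKM of 10.7 and 2.998, 3.57-fold lower (2.99 to 4.27), Krt15 7.56 and 2.59, and Aqp3 3.12 and 1.74. Trp63, the transcription factor of basal cells, had 2.43 and 1.44. Krt4, a keratin of differentiated squamous cells, was the member that was higher, at 0.345 and 1.18. Several leukocyte and mesenchymal markers, given next, were lower in the same library.

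Other cell types that a sort could carry along also differed. Leukocyte markers went both ways. Of 11 measured, 6 lay below 0 and 5 above, with a median of -0.38 at the 0.02 percentile. On the log2(FPKM + 1) scale 4 were at least 1.5-fold lower and 0 higher. The lower ones were Tyrobp (FPKM 3.07 and 0.644), Fcer1g (4.45 and 1.36), Laptm5 (2.15 and 0.679) and Coro1a (1.16 and 0.384). Csf1r (0.984 and 1.80), Cd79a (0.527 and 1.06), Lyz2 (6170 and 7257), Cd74 (1009 and 1163) and H2-Aa (247 and 275), named after their values were seen, were the members above 0. Of these, Lyz2, Cd74 and H2-Aa lay far above every other measured member in both libraries, so leukocytes need not be their source here. Ptprc, the CD45 gene against which lineage depletion is commonly aimed, had FPKM of 0.519 and 0.172. Only 4 mesenchymal markers were measured. Of these, Dcn (11.9 and 3.79) and Mfap4 (3.25 and 0.973) were over 1.5-fold lower, while Col3a1 had 1.39 and 0.746, and Col1a2 1.32 and 1.20. Col1a1 had 0.824 and 0.828. Kdr (9.05 and 5.11) was the only endothelial marker with FPKM of at least 1; Pecam1 had 0.878 and 0.565. None of the 5 erythroid genes listed in the tables used reached FPKM of 1. In contrast, ciliated cell markers were higher, with all 11 measured members above 0, 3 of them at least 1.5-fold, and a median of 0.36 at the 99.88 percentile. Tppp3 had FPKM of 24.98 and 40.2, Ak7 0.899 and 1.87, Dnali1 0.677 and 1.35, and the ciliogenesis factor Foxj1 2.41 and 3.38. Fam183b rested on about 3 reads in the control library, with a ratio of 9.72 (2.97 to 50.01). Neuroendocrine markers stayed inside the random range (median -0.13, percentile 4.47), with Calca at 8.49 and 5.76, Scg5 at 0.711 and 1.28, Pcsk1 at 1.92 and 1.38, and Syp at 1.45 and 1.09. Epcam, used for the sort, had FPKM of 28.2 and 31.0, and Cd24a, the other sort antigen, 127 and 116. Xist, the long RNA of the inactive X chromosome, had 53.9 and 51.9, and the Y-linked Ddx3y was listed at 0 in both libraries.

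**Figure D2:**
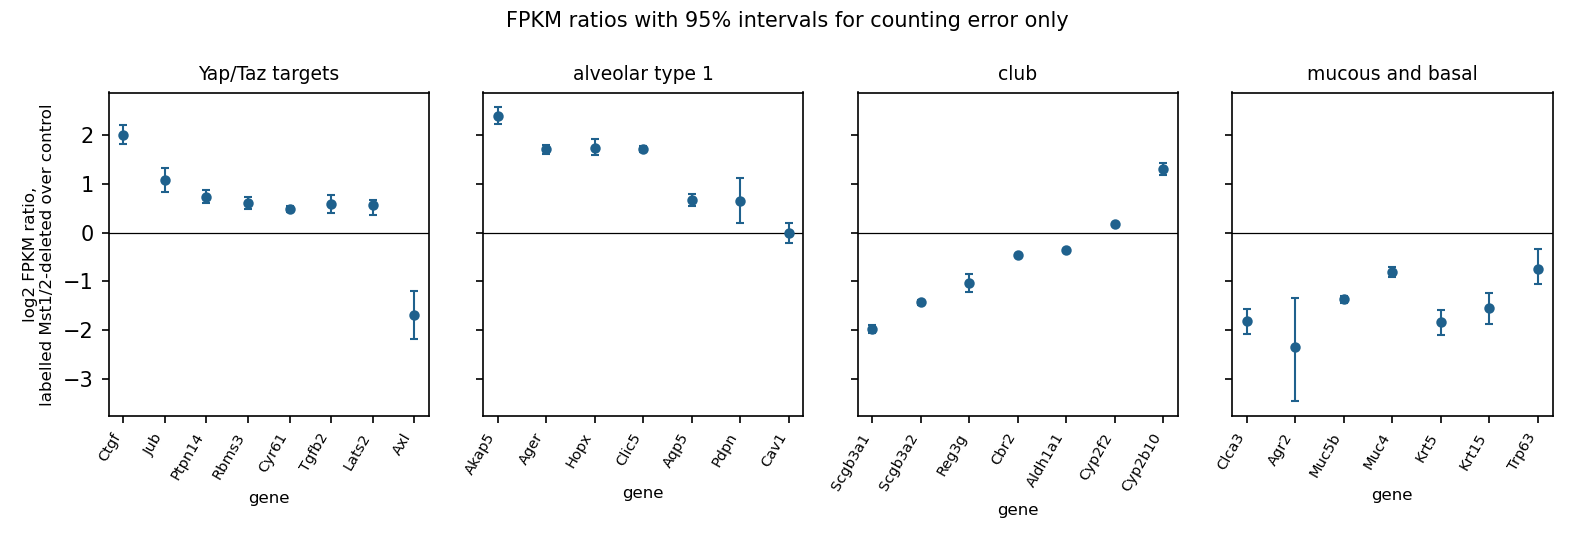
FPKM ratios, on a log2 axis, of the library labelled Mst1/2-deleted over control for selected Yap/Taz targets and cell type markers; points are 1 library per genotype and bars are 95% intervals for counting error only. Ctgf, at a ratio of 4.01, and Ager, at 3.26, lie well above 0 and Scgb3a1, at 0.253, well below it, while Cav1, at 0.995, lies on the line.

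Genes of epithelial structure were modestly higher as lists. The 24 actin and adhesion genes had a median log2 difference of 0.34 above all random lists, with 22 above 0, but none reached 1.5-fold on the log2(FPKM + 1) scale. Among the larger differences were those of Pxn (FPKM 8.51 and 12.7), Ilk (14.7 and 21.5) and Itgb6 (3.44 and 5.31). The 19 junction and polarity genes had a median of 0.25 at the 99.84 percentile. Cldn18 (64.5 and 112), which encodes a tight junction claudin, and Tjp1 (16.6 and 29.0), which encodes ZO-1, were over 1.5-fold higher, and Pard6b had FPKM of 5.63 and 8.17. Both lists were higher together with the alveolar type 1 cell markers.

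Among 26 measured xenobiotic metabolism genes, 5 were at least 1.5-fold lower and 1 higher, with a median of -0.25 below all random lists. The glucuronosyltransferase Ugt1a6a had FPKM of 16.4 and 5.97 (2.74-fold lower, 2.47 to 3.04), Sult1d1 9.70 and 4.01, and Cyp1b1 24.7 and 12.3; Cyp2b10, above, was the member that was higher. Ugt1a6a shares exons with other Ugt1a transcripts, so its level is uncertain. Of this list, 10 genes are also in the club cell list. The cytosolic ribosomal protein list had a median of -0.19 (percentile 0.09), with Rpsa at 77.0 and 55.7, Rplp1 at 68.4 and 51.0, Rplp0 at 46.5 and 35.7, and Rpl37 at 39.2 and 30.3. The oxidative phosphorylation list had a median of -0.10 (0.03), which returned to the random range when random lists were also matched on transcript length (3.15). The members with the largest differences were Cox6c (22.6 and 16.3), Atp5j (68.9 and 54.0), Cox4i1 (18.3 and 14.7) and Ndufb9 (33.9 and 28.6). Across genes, the difference went up with transcript length (Spearman rho 0.170), and the median transcript length was 846 bases in the ribosomal protein list and 999 bases in the oxidative phosphorylation list. The ribosomal protein list still stood apart with length matching (percentile 2.33) and with the length and GC trend removed (median -0.084, percentile 0.49). The glycolysis list, at a median of -0.01 (12.91), and the cholesterol and fatty acid synthesis list, at 0.15 (91.61), did not stand apart as reported. In the latter, Scd2 (27.3 and 48.6) was over 1.5-fold higher, and Acaca had FPKM of 7.95 and 11.7 and Lss 3.67 and 5.001. Eno1 (2.41 and 1.34), whose reads can be shared with pseudogenes, Pdk1 (1.47 and 1.99), Slc2a1 (17.8 and 14.98) and Gapdh (321 and 287) were the glycolysis genes with the largest differences.

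Immune and stress response lists were lower. Of 16 inflammatory genes, 6 were at least 1.5-fold lower and 1 higher (median -0.15, percentile 0.1). Ccl17 (FPKM 2.66 and 0.201), Saa3 (2.42 and 0.251), Tnf (3.32 and 1.12) and Cxcl5 (3.50 and 1.21) had the largest differences, all at low levels; among the 6 members with FPKM of at least 5 the median was 0.10, of opposite sign. The 11 interferon response genes had a median of -0.29 (0.01), with Bst2 (2.63 and 1.28) and Oasl2 (2.34 and 1.13) over 1.5-fold lower, Ifi44 at 1.03 and 0.388, and Ifit3 (1.36 and 3.09) higher. The median of the leukocyte markers was lower in the same library. The 20 immediate early and heat shock genes had a median of -0.17 (0.2), and none differed by 1.5-fold on the log2(FPKM + 1) scale. Ier2 (44.6 and 31.1), Zfp36 (403 and 304) and Egr2 (21.0 and 15.7) were lower, and Dusp1 (195 and 270) was higher. The 12 measured p53 response genes had a median of -0.17 (0.12) with no member at 1.5-fold on the log2(FPKM + 1) scale. Phlda3 had FPKM of 1.92 and 1.07, 1.79-fold lower (1.20 to 2.72) as a plain ratio, Perp 14.04 and 9.91, Ccng1 17.6 and 13.6, and Cdkn1a, which encodes the cell cycle inhibitor p21, 16.5 and 23.4.

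Of the signalling lists, the 9 Notch pathway genes had a median of -0.14 at the 2.34 percentile, which returned to the random range under 3 of the alternatives. Nrarp, a feedback target of Notch, was 1.85-fold lower (1.61 to 2.12; FPKM 9.22 and 4.98), whereas Hes1 (98.7 and 83.5), Notch1 (5.40 and 4.45) and Hey1 (1.12 and 0.769) differed by less than 1.5-fold on the log2(FPKM + 1) scale. EGF receptor ligands and receptors did not stand apart (median 0.03, percentile 24.82); Nrg1 (1.11 and 2.31) was the member over 1.5-fold higher, and Erbb3 had 5.32 and 6.67, Btc 3.64 and 4.54, and Tgfa 4.03 and 3.57. Lung epithelial transcription factors did not stand apart either (-0.02, percentile 5.47) and had no member at 1.5-fold. Nkx2-1, a regulator of lung identity, had FPKM of 74.2 and 88.1, Sox2, a regulator of airway identity, 6.27 and 5.13, Cebpb 7.33 and 5.10, Foxp1 8.46 and 10.7, and Ehf 16.7 and 13.7.

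**Figure D3:**
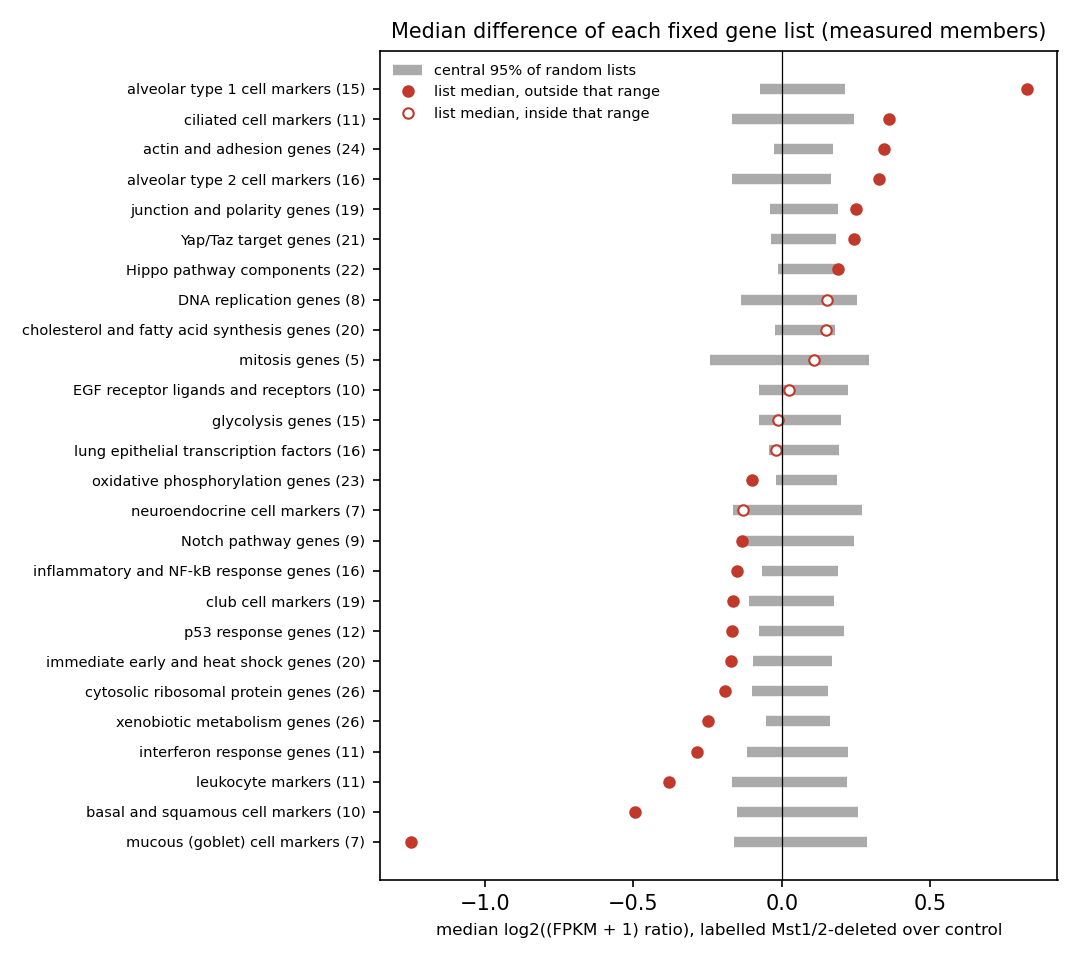
Median log2 difference, library labelled Mst1/2-deleted over control, of each fixed gene list with at least 5 measured members (points, with the number of measured members), and the central 95% of medians of 10000 expression-matched random lists (bars). Alveolar type 1 cell markers (0.83) and mucous cell markers (-1.25) lie farthest from their bars, and 19 of 26 lists lie outside, against 1.3 expected if list members varied independently.

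The largest differences among genes with FPKM of at least 5 included several outside the lists. In the higher direction, Igj, the immunoglobulin J chain gene, was 9.01-fold higher (6.84 to 11.9; FPKM 1.06 and 9.58), Iyd, an iodotyrosine deiodinase gene, 6.02-fold (4.93 to 7.44) and Psca, a surface antigen gene, 5.01-fold (4.12 to 6.07). The steroid dehydrogenase gene Akr1c14 was 4.00-fold higher (3.63 to 4.41), Porcn, which encodes the acyltransferase that modifies Wnt proteins, 3.98-fold (3.50 to 4.56), and Igfbp7, at FPKM of 30.4 and 104, 3.42-fold (3.18 to 3.70). In the lower direction, Gdpd2 was 10.3-fold lower (8.30 to 12.9; FPKM 14.7 and 1.43), Il1f9, an interleukin-1 family cytokine gene, 8.996-fold (6.85 to 11.9), Plunc, a secreted protein gene of upper airway epithelium, 3.53-fold (3.32 to 3.75; FPKM 177 and 49.97), and Chad, which encodes the matrix protein chondroadherin, 3.49-fold (3.22 to 3.79). Acsf2, which overlaps Chad, was also lower, at 29.0 and 15.7. The eosinophil-associated ribonuclease genes Ear10 (16.6 and 0.336) and Ear1 (6.05 and 0.512), the chitinase-like gene Chi3l3 (24.0 and 4.51) and the carboxylesterase gene Ces1f (12.8 and 2.42) belong to families of near-identical copies that share reads, so their individual levels are uncertain. Akr1b3, at 6.77 and 0.0013, overlaps Gm6644 along nearly its whole length, and Gm6644, without status OK, had FPKM of 10.7 and 21.3; how reads were divided between them is not known. The remaining genes of this set were small RNAs listed at 0 in 1 library and supported by at most 28 reads in the other. They were Snord2, Snord49b, Snord100 and Mir3094, listed at 0 in the control library, and Snora61 and Mir1949, listed at 0 in the other.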

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

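Settings that restrict the count to transcripts of at least 300 bases, match random lists on length or remove the length and GC trend were chosen after seeing the data. The counts of genes at least 2-fold higher and lower (75 and 97) became 171 and 183 with a pseudocount of 0.1, 26 and 19 with a pseudocount of 5, and 45 and 34 with FPKM of at least 5, because the added constant and the filter set how many low genes can pass. After conversion to TPM they were 295 and 479, since TPM values are larger than FPKM against the same pseudocount and filter. At 1.5-fold they were 300 and 258, and at 4-fold 13 and 16. With transcripts of at least 300 bases 64 genes were lower, and with status OK as well 48 were higher and 60 lower. Scaling to the same upper quartile shifted all genes by -0.10 on the log2 scale.

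Of the 19 lists that stood apart, 13 kept the same side in every alternative run. With the filter at FPKM of 5, lists left with fewer than 5 members were not compared. The leukocyte, basal and squamous, ciliated and interferon lists were among these, so that filter did not test them. The leukocyte markers that passed it, Lyz2 (log2 difference 0.23), Cd74 (0.20) and H2-Aa (0.15), were above 0, against a list median of -0.38. For the lists outside the 13, the cause was not tested. The Hippo component median was 0.16 (percentile 92.2) with the highest row per symbol, 0.18 (92.3) at FPKM of 5 and 0.17 (95.7) with the trend removed. The Yap/Taz target median was 0.13 after conversion to TPM (93.5), 0.13 without a filter (96.5) and 0.18 with the trend removed (97.0). The club cell median was -0.017 (8.48) with the trend removed, and the inflammatory median turned to 0.10 (65.2) at FPKM of 5, where 6 members are left. The Notch median was -0.054 (4) with a pseudocount of 5, -0.19 (2.87) after median scaling and -0.20 (2.99) after upper quartile scaling. The oxidative phosphorylation median of -0.10 moved to percentile 3.15 with length matching. Lists that came to stand apart were mitosis at 0.22 with TPM (98.5) and 0.11 without a filter (98.4), lung transcription factors at -0.046 without a filter (2.09) and -0.019 with length matching (2.46), and glycolysis at -0.061 with the trend removed (2.22). For single named genes, 783 alternative values stayed within the counting interval and 153 moved beyond it, and 0 of the genes with a 2-fold difference changed sign. The planned count with non-overlapping FPKM intervals could not be run, because the tables used give no intervals, and with 1 library per genotype no library could be left out. No paired analysis was possible because each genotype has 1 pooled library. Differences at low FPKM rest on few reads, and the depth says nothing about variation between mice.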

Other observations

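The genes and lists in the first 2 paragraphs, and all tests in the paragraphs after them, were chosen after the values were seen. Further abundant genes were at least 2-fold apart. In the higher direction, the intracellular chloride channel family gene Clic3 had FPKM of 68.5 in the control library and 174 in the library labelled Mst1/2-deleted, the peripheral myelin protein gene Pmp22 14.97 and 44.3, and Cryab, which encodes a small heat shock protein, 18.8 and 46.2. Msn (33.7 and 78.1), which encodes moesin, a linker of membrane and actin, Fhl1 (23.1 and 54.8), Sparc (51.4 and 110), Fgfbp1 (20.8 and 44.0) and the lipid-binding protein gene Sec14l3 (112 and 228) were also higher. In the lower direction were the matrix and airway genes given in the report, and also Rpph1 (54.2 and 22.1), Ly6a (34.8 and 16.1) and Lpar3 (27.2 and 12.6). The complement gene C3 had FPKM of 95.7 and 37.7, the immunoglobulin transporter gene Pigr 42.9 and 15.8, the peptidoglycan recognition gene Pglyrp1 20.1 and 7.05, and the lipopolysaccharide co-receptor gene Cd14 21.9 and 9.13. Of 12 secreted or surface defence genes, listed from these values, 12 were at least 1.5-fold lower, with a median log2 difference of -1.25, and 3 of the 12 are also in the lists of the report. The iron-binding lipocalin gene Lcn2 was the most abundant, at 369 and 236.

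A list of 21 macrophage-associated genes was written mostly from genes seen to be lower. Of its 17 measured genes, 16 were at least 1.5-fold lower, with a median log2 difference of -1.21, and 6 of the 21 are in the lists of the report. They included Chi3l3 at FPKM of 24.0 and 4.51, Ear10 at 16.6 and 0.336, Ctss at 5.69 and 1.62, and Srgn at 5.08 and 2.06. Leukocyte markers that the list leaves out went both ways. Csf1r was higher (0.984 and 1.80, ratio 1.83 with an interval of 1.43 to 2.37), while Ptprc (0.519 and 0.172) and Coro1a (1.16 and 0.384) were lower. Lyz2 (6170 and 7257) was also higher, but at a level far above Ptprc, so leukocytes need not be its source here. A list of 17 proximal airway genes, 13 of which are in the lists of the report, had a median of -1.25 with 14 at least 1.5-fold lower. Since these lists were written from the values, their medians are no independent evidence.

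The higher alveolar type 1 cell markers might come from transcript length or GC bias, from more type 1 cells in the pool, at which the sort for CD326 and intermediate CD24 was not aimed, or from a change in the sorted cells. Bias is argued against, because removing the length and GC trend left the list median at 0.78 on the log2 scale, above all random lists. Of 7 transcripts typical of type 1 cells, 5 were at least 1.5-fold higher on the log2(FPKM + 1) scale, with Pdpn (FPKM 1.44 and 2.26) and Cav1 (6.32 and 6.29) the exceptions. By its plain FPKM ratio of 1.57 (1.14 to 2.17), Pdpn also passed 1.5-fold. Cav1 goes against a larger share of type 1 cells as the only source of the pattern, but endothelial and mesenchymal cells also express it. Of their markers, Kdr (9.05 and 5.11), Dcn (11.9 and 3.79), Mfap4 (3.25 and 0.973), Col3a1 (1.39 and 0.746) and Pecam1 (0.878 and 0.565) were lower. Col1a1 (0.824 and 0.828) and Col1a2 (1.32 and 1.20) differed little. A larger share and a change within the sorted cells therefore cannot be told apart. The genotype effect that the design names stays open and has no replicate.

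The lower Scgb3a1 and Scgb3a2 might reflect fewer club cells, less large-airway epithelium in the pool, or lower expression in the same cells. A plain loss of club cells is argued against: the 17 other measured club cell markers had a median log2 difference of -0.076, with quartiles of -0.42 and 0.20, against -1.43 for Scgb3a2. As for less large-airway epithelium, the basal and squamous markers had a median of -0.50 and the mucous markers were also lower, but the ciliated markers, which large airways also hold, had a median of 0.36. The sort was meant to leave out ciliated cells, so their markers decide little, and a smaller share of large-airway epithelium cannot be told apart from lower expression. The genotype effect stays open and was not tested with replicates.

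The higher Yap/Taz target list may reflect transcript length or GC bias, or Yap/Taz activity. Removing the length and GC trend took the median from 0.24 to 0.18 and its percentile to 97.0, so the call ended, while random lists matched on length left it at 99.8. A contribution of length or GC therefore cannot be told apart from an effect of genotype for the list, because the median kept most of its size but lay near the limit. The rule for reading this test was changed after its value was seen, from length or GC fitting as the source to leaving it open. Alveolar type 1 cells also express targets of Yap, and that source was not tested separately.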
